A study of Mus musculus with 2 samples.

How the data were processed

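Single-cell RNA sequencing was carried out on CT26 tumours, a mouse colorectal carcinoma line grown under the skin of BALB/c mice. There was 1 library from vehicle-treated tumour and 1 from tumour treated with WQ-2101, labelled as an inhibitor of PHGDH, the first enzyme of serine synthesis. Per the labels' protocols, tumours were dissociated with enzymes, strained and freed of red cells, and the whole suspension was loaded on a droplet platform that reads 3' ends. No sort is recorded, both libraries carry the same batch label, and the number of mice behind each library is not given in the sources used here.

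The values used were raw UMI counts per gene and barcode, deposited by the authors without normalisation. The matrices were made with Cell Ranger 7.2.0, per the file headers, whereas the submitters' processing notes list Cell Ranger 2.2.2. Those notes give GRCm38 as the genome build. The annotation release, the treatment of intron reads and any correction for doublets or free RNA are not given in the sources used here. The lowest total of any deposited barcode was 500 UMIs. Gene coordinates were taken from the GENCODE vM21 annotation of GRCm38 by Ensembl identifier, and 32158 of 32285 identifiers (99.6%) had an entry.

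Everything below was computed from those counts with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs. Scrublet was run per library, with an expected rate of 0.8% per 1000 barcodes, and its own threshold called 3.60% of scored vehicle barcodes and 4.76% of scored WQ-2101 barcodes. The filters removed 22 and 6 barcodes for low UMIs or genes, 139 and 90 for mitochondrial share, and 516 and 863 as doublets, in the vehicle and WQ-2101 libraries. This left 13697 vehicle cells with a median of 10757 UMIs and 17183 WQ-2101 cells with a median of 8057 UMIs.

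Counts per cell were scaled to 10000 and log-transformed. The 2000 most variable genes gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 over both libraries together, with no batch integration. Clusters were named from marker lists for 15 cell classes that were fixed before the data were examined. The rule that turns markers into names was not fixed then. A total of 4 naming rules were tried, each written after tables of clusters with their cells per library had been seen. The first, a mean z-score, left nearly all tumour clusters without a name. The second, the mean of each marker's level over its highest level in any cluster, named a mixture of macrophage and T cell RNA as macrophages and, in some alternative clusterings, a Col3a1-high tumour cluster as fibroblasts. The third used a root mean square and called most tumour clusters mixed with NK cells. The fourth was kept: it returned to the mean, needed 3 usable markers per class, and left out tumour and stromal markers that peak in a cluster where Ptprc, the pan-leukocyte gene, reaches 20% of its highest level. A cluster stayed without a class where its leading genes held more markers of another class, where a tumour cluster had Ptprc above 5 times the tumour median, or where a non-lymphocyte cluster scored 0.2 or more on T or B cell markers. These thresholds were set after the data were seen. Cluster 0 was kept as tumour although Col3a1 and Fbn1, also fibroblast genes, lead it over all other cells.

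The clusters left without a class were 11 (1.28% of vehicle and 0.111% of WQ-2101 cells), 13 (1.00% and 15.0%), 19 (1.05% and 0.739%) and 20 (0.161% and 1.05%). Macrophages and monocytes, T cells and dendritic cells were clustered again at resolution 0.6. The rule for naming sub-clusters was tightened once, after their table had been seen, to need an own marker among the 10 leading genes. Sub-cluster sizes were compared only where at most 1 of the leading genes differed 1.5-fold or more between the libraries, and any other sizes given carry no conclusion.

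With 1 library per group there is no measure of variation between animals, so no test of the treatment was made and no p-value is given. Shares of cells have exact Clopper-Pearson 95% intervals. For genes, the raw counts of a class were summed per library and divided by the class's UMIs (CPM), with exact Poisson intervals and an exact conditional interval for the ratio. All intervals cover counting error only. The log2 ratio is that of WQ-2101 CPM plus 5 over vehicle CPM plus 5. Classes were compared with at least 100 cells in each library, namely tumour, macrophage and monocyte, T cell, dendritic and fibroblast.

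A total of 35 gene lists were fixed before the data were examined. List members needed a mean of 5 CPM and a list 4 such members. A member counted as higher or lower at 1.5-fold or more in CPM plus 5. Each list's median log2 ratio was set against 10000 random lists of equal size, drawn with replacement within 20 bins of expression, and its percentile describes these libraries only. Of 163 medians computed over lists and classes, 53 are described and were carried through the alternatives, and 6 more are given among the further observations. Medians of ATF4 targets and heat shock genes in further classes are given beside the tumour values, without the alternatives. All were chosen after the list results had been seen. Named genes followed a rule fixed before the data were examined: the 10 highest and 10 lowest log2 ratios in tumour, macrophage and T cell classes, and the 4 highest and 4 lowest in other classes. They needed a mean of 20 CPM and a UMI in 10% of the cells of the library with the higher level. Mitochondrial, ribosomal protein, unnamed, receptor segment and haemoglobin genes and markers of other classes were left out. Up to 2 highest and 2 lowest members of each described list, and Phgdh, Psat1 and Psph, were added.

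The steps from summed counts to ratios and lists were tested on simulated counts with 200 changed genes. Sums per class were drawn as Poisson counts from a profile shared by both libraries, so only counting error was simulated. Clustering, naming, free RNA and variation between animals were not, so the shares below are no error rates for the results. In macrophages (5826 genes) and tumour cells (6660 genes), 100% of the genes changed 4-fold, 2-fold, 0.5-fold and 0.25-fold passed the 1.5-fold rule in the right direction, and 0% of unchanged genes did. In T cells (6101 genes), 98% of 2-fold and 0.5-fold genes and 100% of 4-fold and 0.25-fold genes passed, against 0.424% of unchanged genes.

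Alternatives fixed before the data were examined changed the mitochondrial, UMI and doublet filters, the clustering, the denominator, depth, scaling, cell weights, pseudocount, expression minimum and free RNA. Alternatives chosen after seeing the data counted clusters 13 and 20 as tumour, left out cluster 0 or dendritic sub-clusters 4 and 7, gave each cluster the same share in both libraries, or took shares over cells with a class.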

Results

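Whole CT26 tumours were profiled by droplet single-cell RNA sequencing on day 17 after implantation. Daily intraperitoneal dosing, with vehicle or with 20 mg/kg of WQ-2101, began once tumours measured about 100 mm³. There was 1 library per group, so no value below has a replicate error. The vehicle library held 14374 barcodes and 184754398 UMIs, and the WQ-2101 library 18142 barcodes and 185587327 UMIs. For a class with no cell in a library, the limit on its share was set at 3 cells over the kept cells. That is 0.0219% in vehicle and 0.0175% in WQ-2101, and it is not a Clopper-Pearson interval.

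The series title links PHGDH inhibition in tumour cells to macrophages, and the first question was which cells the tumours held. Macrophages and monocytes made up 32.9% of vehicle cells (95% interval 32.1 to 33.7) and 21.0% of WQ-2101 cells (20.4 to 21.6), a ratio of 0.639. Neutrophils were 2.15% of vehicle cells and 0.547% of WQ-2101 cells, a ratio of 0.255 (0.20 to 0.323), or 0.431 among cells with at least 1000 UMIs. Their own summed markers were 35990 CPM in vehicle and 101263 in WQ-2101, so the neutrophils compared were not alike. The share of B cells was higher in WQ-2101, with 20 cells in vehicle (0.146%) and 356 in WQ-2101 (2.07%), a ratio of 14.2 (9.05 to 23.5). Tumour cells were 51.8% and 51.1%, and T cells 4.77% and 4.42%, with a ratio of 0.927 (0.833 to 1.03).

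Dendritic cells, which present antigen to T cells, were 1.91% of vehicle and 1.45% of WQ-2101 cells. NK cells were 0.686% and 0.611%, fibroblasts 1.53% and 1.44%, and endothelial cells 0.562% and 0.396%. The endothelial cluster also scored 0.950 on markers of mural (vessel wall) cells, with their marker Rgs5 among its leading genes. Mural cells are thus not separated from it. Cells without a class were 3.49% of the vehicle and 16.9% of the WQ-2101 library, where most were in cluster 13, and this lowers every other WQ-2101 share. Over cells with a class the macrophage and monocyte ratio was 0.742 and the T cell ratio 1.08. Over immune cells alone the ratios were 0.903 for macrophages and monocytes, and, in the other direction, 1.31 for T cells, 1.26 for NK cells and 1.08 for dendritic cells.

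**Figure D1:**
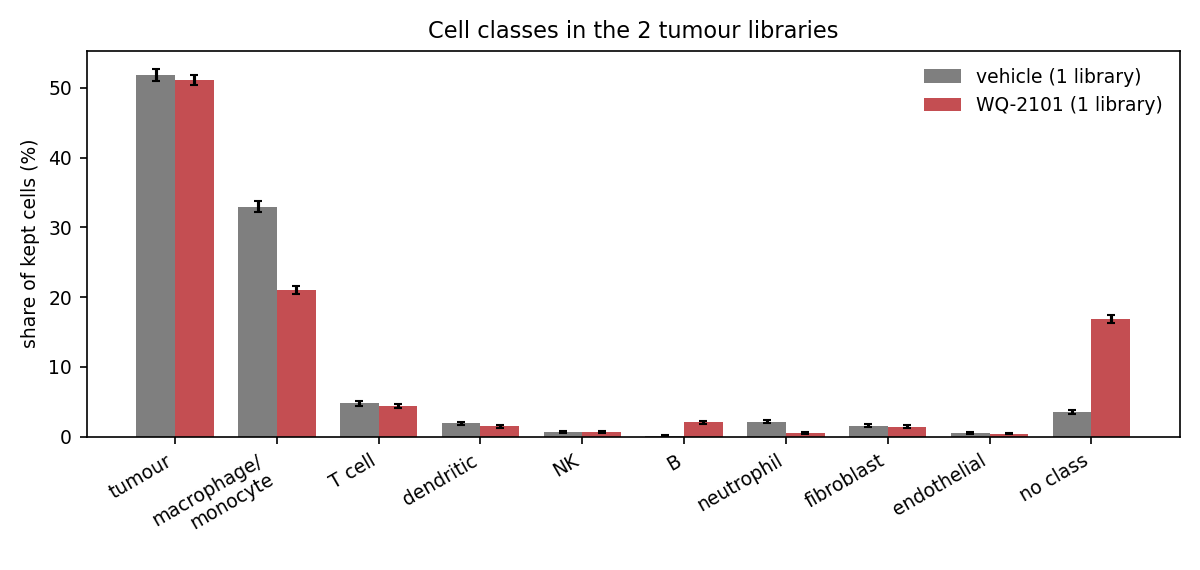
Share of kept cells (%) in each cell class in the vehicle and WQ-2101 libraries, 1 library each, with exact 95% intervals for counting error. Macrophages and monocytes take 32.9% of vehicle and 21.0% of WQ-2101 cells, while cells without a class take 3.49% and 16.9%.

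In tumour cells, genes of hypoxia, interferon gamma, glycolysis and antigen presentation stood higher in the WQ-2101 library. The hypoxia list had a median log2 ratio of 0.62, with 7 of 13 members higher and 0 lower. It includes Ankrd37 (17.4 CPM in vehicle, 43.8 in WQ-2101) and Pdk1, a kinase that diverts pyruvate from mitochondria (21.3 and 43.0). The interferon gamma list had a median of 0.59, with 8 of 16 members higher and 0 lower, among them the T cell attractant Cxcl9 (14.1 and 30.6). Socs1, a brake on this pathway, was 45.8 and 37.2.

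The glycolysis list had a median of 0.37, and 1 of 15 members, Pfkl (53.4 and 93.0 CPM), passed 1.5-fold. Pgk1 was 542 and 796. MHC class I genes had a median of 0.33, with 2 of 13 members higher, the proteasome subunit Psmb9 (30.8 and 52.2) and the peptide transporter Tap1 (25.6 and 43.4). MHC class II genes had the highest median of the lists described in tumour cells, 0.94, with 4 of 7 members higher: Cd74 (52.5 and 119), H2-Eb1 (30.0 and 67.7), H2-Aa (34.8 and 72.6) and H2-Ab1 (36.5 and 74.6). Macrophages and dendritic cells carry these transcripts in abundance. Summed macrophage markers in the same tumour cells were 251 CPM in vehicle and 258 in WQ-2101, with C1qa at 23.7 and 34.1 and Lyz2 at 93.2 and 80.1. Scaled to these markers, free RNA was estimated at 5.56% and 8.02% of tumour RNA, and macrophages and dendritic cells would bring 53.7 and 81.3 CPM of Cd74.

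Targets of ATF4, the transcription factor of amino acid shortage, had a median of 0.24, with 4 of 24 members higher and 0 lower, including Trib3 (15.4 and 32.0 CPM) and Ddit4 (17.8 and 30.9). Atf3 was 282 and 281. The ATF4 median also lay above the range of random lists in macrophages (0.16), dendritic cells (0.34) and fibroblasts (0.29), and inside it in T cells (-0.03). It is thus not particular to tumour cells. Serine and one-carbon genes had a median of 0.16 at percentile 99.98 of random lists, and none of the 16 members passed 1.5-fold. Type I interferon genes had a median of 0.15 with 1 of 18 members higher. Heat shock genes had 0.16 with 3 of 10 higher, led by the chaperones Hsph1 (120 and 244) and Hspa1b (52.1 and 95.6). Heat shock medians lay above the range of random lists in every compared class, including dendritic cells (0.45) and fibroblasts (0.78).

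Lower medians belonged to glutathione and redox genes (-0.19, 0 of 16 past 1.5-fold), which hold both subunits of the glutathione-making ligase, Gclm (74.6 and 55.7) and Gclc (62.0 and 46.8). Matrix and mesenchymal genes had a median of -0.17, with 2 of 16 higher and 1 lower: Tnc (34.3 and 66.3) and Snai2 (21.7 and 36.2) were higher, and Mmp9 (10.3 and 4.89), named after its value was seen, was lower. Col3a1 was 518 and 375. The matrix median lay inside the random range with members of at least 20 CPM (-0.12). Nucleotide synthesis genes had a median of -0.12 and proliferation genes -0.11, with no member past 1.5-fold. Both lay inside the random range with every cluster at the same share (-0.054 and -0.059) and with cells weighted alike (-0.081 and -0.027). Oxidative phosphorylation (-0.07) and tumour chemokine genes (0.01) lay inside the range of random lists, although Cxcl1, which attracts neutrophils, was 533 and 333. Immediate early genes, which tissue dissociation induces, had a median of -0.23, or -0.11 and inside the random range with every cluster at the same share.

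The highest named gene in tumour cells was Slc7a2, a transporter of arginine and lysine (ENSMUSG00000031596, GRCm38 chromosome 8, 40862396 to 40922308). It stood at 20.3 CPM in vehicle and 73.9 in WQ-2101, a log2 ratio of 1.64. Slurp1 (1.52), Ankrd37 (1.13), Arhgap29 (1.11), Cd74 (1.11), H2-Eb1 (1.06), the metal-binding Mt1 (1.05), Hsph1 (1.00), H2-Aa (0.96) and H2-Ab1 (0.94) followed. Lowest were Lsmem1 (-1.09), the inhibitor of differentiation Id3 (-1.03), Nfatc2 (-0.96), Fosb (-0.85), Fos (-0.71), the cold-inducible Cirbp (-0.71), Tex14 (-0.70), Hist1h4i (-0.68), Sema5a (-0.67) and Sertad1 (-0.67). Keratin Krt14, also a keratinocyte marker, was 90.2 and 199 CPM. Krt14 and Mt1 also lead tumour cluster 5 over all other cells, and that cluster was 3.18% of vehicle and 9.75% of WQ-2101 cells.

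Macrophages and monocytes, the class the series title names, carried more MHC class II and interferon gamma transcripts in the WQ-2101 library. MHC class II genes had a median log2 ratio of 0.51, with 2 of 8 members higher, and H2-Aa was 1402 and 2132 CPM. Interferon gamma genes had a median of 0.42, with 7 of 19 higher and 0 lower, including the GTPase Gbp5 (15.9 and 35.3) and Upp1 (26.0 and 53.9). Hypoxia genes had a median of 0.34 with none of 13 past 1.5-fold, and the vessel growth factor Vegfa was 163 and 242. The chemokine genes Ccl2 (740 and 309) and Ccl12 (367 and 162), which draw monocytes, were lower.

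Inflammatory macrophage genes had a median of 0.24, with 3 of 16 higher and 1 lower. Ccl5 (61.5 and 132) and the nitric oxide synthase Nos2 (22.1 and 46.0) were higher and Tnf (184 and 106) was lower. Alternative macrophage genes had a median of -0.15, with 2 of 15 higher and 1 lower: the lectin Mgl2 was 76.0 and 221, and Chil3 438 and 151. Chil3 is also a monocyte marker, and Mgl2 also leads the dendritic cluster. Of the checkpoint genes (median 0.07, inside the range of random lists, 2 of 10 higher), Cd274, which encodes PD-L1, was 138 and 225. Type I interferon genes had a median of 0.12, with 4 of 22 higher, among them the RNA sensor Ifih1 (78.5 and 186). MHC class I (0.22), heat shock (0.23) and glycolysis genes (0.18) also lay above the range of random lists.

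The title also names macrophage epigenetic programs. The list of histone and DNA modifiers had a median log2 ratio of 0.08 at percentile 99.06, and none of its 39 members passed 1.5-fold. It lay inside the random range with every sub-cluster at the same share (0.045) and with members of at least 20 CPM (0.0554). The DNA methyltransferase Dnmt3a was 24.7 and 36.3 CPM, Tet2 103 and 126, the deacetylase Sirt1 29.4 and 22.2, and the demethylase Kdm6b 141 and 113. These are transcripts of the enzymes and do not measure histone or DNA marks.

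Cholesterol synthesis (-0.24), glutathione (-0.17), NF-kB target (-0.11) and immediate early genes (-0.27) had lower medians in macrophages, and Hmox1, which degrades haem, was 322 and 224. Lipid-associated (-0.01), complement and scavenger (0.07) and serine genes (0.02) lay inside the range of random lists. The highest named gene was Cadm1 (ENSMUSG00000032076, GRCm38 chromosome 9, 47530173 to 47857637), at 14.3 and 60.8 CPM. After Cadm1, with a log2 ratio of 1.77, came Hspa1b (1.58), the fusion protein gene Dcstamp (1.48), Mgl2 (1.48), Ifitm1 (1.42), Tnfrsf9 (1.28), P2ry14 (1.23), Ifih1 (1.19), Itga9 (1.08) and Ccl5 (1.05). Lowest were Chil3 (-1.51), Hopx (-1.28), Ccl2 (-1.25), Ccl12 (-1.15), Cav1 (-0.88), Cxcl3 (-0.87), Rfx2 (-0.82), Cxcl14 (-0.81), Ly6c2 (-0.77) and Tnf (-0.77).

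Within this class, the sub-cluster led by MHC class II genes and Dcstamp was 12.8% of vehicle (11.9 to 13.8) and 22.5% of WQ-2101 cells (21.1 to 23.8). Its leading genes H2-Eb1, H2-Ab1, H2-Aa and Il1r2 also lead the dendritic cluster. Whether cells like dendritic cells are part of this sub-cluster was not tested. Monocytes, marked by Plac8 and Ly6c2, were 9.03% and 6.20%. A larger sub-cluster with monocyte genes, led by Fn1, Ccr2, Hopx and Chil3, held 996 of 4509 vehicle and 385 of 3612 WQ-2101 cells. Because 3 of its leading genes differed between the libraries, its size is not compared. Cycling cells were 9.51% and 10.7%, and a sub-cluster led by Atf3 and Jun was 6.68% and 5.20%. NF-kB targets lay inside the random range at a minimum of 1000 UMIs (-0.081) and at Leiden resolution 2.0 (-0.0926). The median of alternative macrophage genes moved inside the random range at a minimum of 1000 UMIs per cell (-0.076) and at Leiden resolution 2.0 (-0.091).

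**Figure D2:**
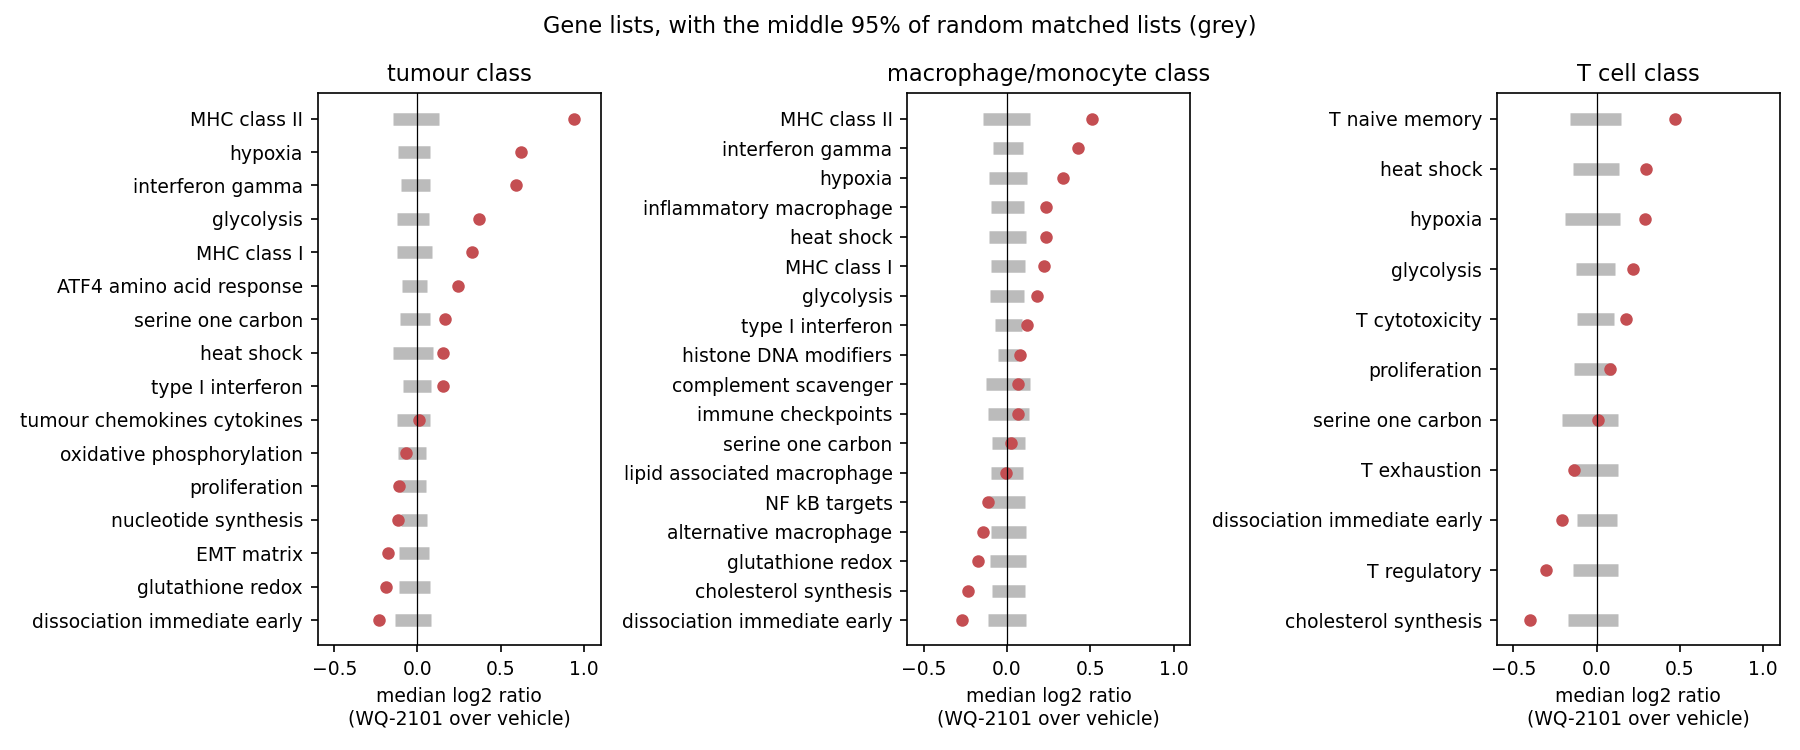
Median log2 ratio of WQ-2101 over vehicle for each described gene list (points) in tumour, macrophage and monocyte, and T cells, with the middle 95% of 10000 random lists matched on expression (grey bars). In tumour cells the MHC class II, hypoxia and interferon gamma medians, 0.94, 0.62 and 0.59, lie farthest above the grey bars.

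T cells of the WQ-2101 library carried more transcripts of naive and memory cells. The naive and memory list had a median log2 ratio of 0.47, with 5 of 11 members higher and 0 lower, including the lymphoid exit receptor S1pr1 (26.7 and 61.0 CPM) and the transcription factor Tcf7 (46.2 and 99.2). Cytotoxicity genes had a median of 0.17, with 5 of 16 higher and 0 lower: the granzyme Gzmd was 26.2 and 150, and Gzmb 538 and 492. Ifng, the interferon gamma gene itself, was 171 and 373. Regulatory T cell genes had a median of -0.30, with Il10 at 34.7 and 16.0 and Il2ra at 223 and 226.

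Exhaustion genes (-0.14) and proliferation genes (0.08) lay inside the range of random lists, as did serine genes (0.01), although Gldc was 31.1 and 16.9. Cholesterol synthesis genes had a median of -0.40, with 3 of 16 lower and 1 higher, including Sqle (34.2 and 17.4). Glycolysis (0.22), hypoxia (0.29) and heat shock genes (0.30) had higher medians and immediate early genes (-0.21) a lower one. The highest named genes were Cmah (1.77), Aff3 (1.72), Hspa1b (1.39), Ifng (1.11), S1pr1 (1.06), Tcf7 (1.02), Fgf13 (1.01), Lef1 (1.00), Klf3 (1.00) and Sidt1 (0.98). Among the lowest were Fn1 (-1.52), Arg1 (-0.94), Cd81 (-0.93), Il1b (-0.90), Ipmk (-0.89), Cxcl10 (-0.85), Gtf2h1 (-0.83), Lmna (-0.81) and Sqle (-0.81). Over the alternatives Fn1 ran from -3.68 to -0.54, Arg1 from -1.33 to -0.52, Cd81 from -1.80 to -0.55 and Il1b from -2.51 to -0.19. Each of these thus fell under 1.5-fold in some alternative. Fn1, Arg1 and Il1b are also macrophage transcripts, and summed macrophage markers in these T cells were 996 and 915 CPM.

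Naive cells numbered 50 of the vehicle T cells and 183 of the WQ-2101 T cells, and regulatory cells 109 and 79. Leading genes of both sub-clusters differed between libraries, so no conclusion is drawn from their sizes. With every sub-cluster at the same share in both libraries, the regulatory list was 0.12, inside the random range. The naive and memory median then fell to 0.17, with Tcf7 at 0.43, S1pr1 at 0.56 and Lef1 at 0.58. With each library clustered on its own, the glycolysis (0.090), hypoxia (0.087), regulatory (-0.0318) and heat shock lists (-0.0072) lay inside the random range. Exhaustion (0.19) and proliferation genes (-0.23) then changed sign and left that range.

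Phgdh, the gene of the enzyme that WQ-2101 is labelled to inhibit, stood at 291 CPM (288 to 294) in vehicle tumour cells and 264 (261 to 267) in WQ-2101 tumour cells. Psat1, the next enzyme of the pathway, was 99.8 and 119, and Psph, the last, 50.8 and 68.5. In macrophages Phgdh was 17.3 and 21.0. The tumour marker Hmga2 there was 46.7 and 62.8, while summed tumour markers, which include Cd24a, were 236 and 186. Free tumour RNA is thus not separated from Phgdh in macrophages. In T cells Phgdh was 95.6 and 114, a log2 ratio of 0.24 that became -0.24 with each library clustered on its own. Transcript levels do not measure inhibition of the enzyme.

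Dendritic cells of the WQ-2101 library carried more macrophage and fibroblast RNA: summed macrophage markers were 1888 and 3023 CPM, and fibroblast markers 171 and 412. Hypoxia genes had a median log2 ratio of 0.70, with 7 of 13 higher, and unfolded protein genes one of -0.37, with 3 of 16 lower, led by the chaperone Dnajb9 (56.2 and 23.2 CPM). MHC class II genes had a median of -0.23, interferon gamma genes 0.23 and proliferation genes 0.45. Named genes were Lhfp (2.37), Timp3 (2.24), the collagen chaperone Serpinh1 (2.12) and Ly6c1 (1.96), and Fh1 (-1.24), Tnni2 (-1.19), Qpct (-1.18) and Nars2 (-1.14). Sub-clusters 4 and 7, led by tumour and stromal or by macrophage genes, held 6 and 11 vehicle cells and 22 and 32 WQ-2101 cells. Without them the hypoxia median was 0.37. Proliferation (-0.057), MHC class II (-0.036) and interferon gamma genes (0.0875) then lay inside the random range. Lhfp was then 0.70, Timp3 1.02 and Serpinh1 0.88, and Iigp1 and Ube2c, at 1.31 and 1.24 with them, were -0.49 and -0.080. Phgdh was 31.2 and 54.7 CPM with them and 18.5 and 23.8 without.

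Fibroblasts of the WQ-2101 library carried fewer matrix transcripts and more RNA of other cells. Summed fibroblast markers were 29020 CPM in vehicle and 12839 in WQ-2101, while tumour markers in the same cells were 339 and 716 and macrophage markers 602 and 1470. The matrix list had a median log2 ratio of -1.39 (-1.89 to -0.68 over the alternatives, smallest with free RNA subtracted), with 15 of 16 lower, including Postn (3502 and 1111 CPM) and Lrrc15 (243 and 47.3). MHC class II (1.56) and proliferation genes (1.05) had higher medians beside that other RNA. Once free RNA, put at 29.8% and 58.0%, was subtracted, no counts of Cd74, H2-Aa and Mmp12 were left in either library. Their log2 ratio of 0 is thus a floor and does not decide whether free RNA made up their higher level. Named genes were Myoc (3.10), Slurp1 (2.92), Rpgrip1 (2.53) and Mmp12 (2.18), and Igfbp5 (-4.26), Reg3g (-3.22), Spp1 (-2.90) and Col23a1 (-2.82). Slurp1 was also among the highest named genes in tumour cells, and Rpgrip1 leads cluster 13 over all other cells. Phgdh was 76.8 and 192 CPM, and tumour RNA in these fibroblasts is not separated from it.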

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

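The tests of doublets, depth and mixed RNA for cluster 13, both tests for B cells and the subtraction of free RNA for MHC class II were chosen only after the result was seen, and the spread of members was added to the first MHC class II test after its value was known.

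Cluster 13 and cluster 20 are cells that no comparison of gene levels above uses, and they count in the shares only as cells without a class. Cluster 13, which carries tumour and leukocyte RNA together, held 15.009% of WQ-2101 cells and 1.00% of vehicle cells. Cluster 20, with tumour genes and the granzyme genes Gzmd and Gzmg, held 1.04755% and 0.161%.

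For cluster 13, doublets of a tumour cell and a macrophage are argued against by its median UMIs, 0.350 times that of tumour cells, and lower depth by a share ratio of 18.7 after both libraries were thinned to the same median. Free RNA of the whole library, as predicted in advance, called for a like level of macrophage and T cell markers, and their ratio was 1.66 (1.58 to 1.75), outside the preset bound of 1.5. A wider form, droplets that mix RNA of all classes from free RNA or broken cells, was written once those values were known, with bounds also set then. Markers of the 10 classes lay between 0.551 and 1.21 times their level over all kept cells, while in tumour cells the lowest was 0.0802. Such a mixture may thus account for the cluster. These levels are sums over the cluster, and all kept cells include it. They do not separate droplets that each mix all classes from a pool of droplets with different pairs of classes. Malat1, a nuclear RNA, was 2807 CPM in the cluster against 4942 in other cells, a value for which no bound was set. The mixture stays a hypothesis, since an effect of treatment on cell breakage was not tested and the unfiltered barcodes are not analysed here.

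For B cells, the minimum of UMIs per cell is argued against by a share ratio of 9.95 at a higher minimum. Lymph node or blood in the WQ-2101 sample would also bring naive T cells, and these had a share ratio of 2.92 (2.12 to 4.07). Leading genes of that sub-cluster differed between the libraries, so this ratio does not decide and that source stays open. A treatment effect on B cells stays open and untested as well, since 1 library per group cannot separate it from what was dissected.

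For MHC class II genes in tumour cells, a larger interferon gamma cluster is argued against, since the median log2 ratio was 0.90 with every tumour cluster at the same share. Free RNA of macrophages and dendritic cells was to be excluded at a median of 2 times the level that macrophage markers predict. The WQ-2101 median was 2.06, past that bound, with members' quartiles of 1.64 and 3.04, and the vehicle median was 1.404, within the 1.5 that free RNA predicts, so that test alone does not decide. After subtracting free RNA the median log2 ratio over the 7 members was 1.196 with the profile of all kept cells and 1.246 with that of cluster 13. The lower quartiles, 0.49 and 0.47, stayed above the random limits of 0.13. They rest on H2-DMa and H2-DMb1, already at 3.56 and 6.65 times the predicted level in vehicle, which the subtraction changes little. Cd74 in vehicle, at 52.5 CPM, did not exceed the 53.7 predicted. Under this scaling alone, free RNA as the whole cause is argued against. C1qa and Lyz2 moved in opposite directions in these cells, and scaling to single markers was not run. A part from free RNA stays open, since both profiles stand in for one that was not measured, and so does expression by tumour cells under treatment, which was not tested.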

How the results depend on the processing

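Alternatives on clusters 13 and 20, cluster 0, dendritic sub-clusters, equal shares or cells with a class were chosen only after the result was seen. No paired analysis was possible with 1 library per group. No result comes from a test, so only counting error and these choices are covered. A pseudocount of 1 CPM and scaling by 0.983 to 1.015 could not reverse a 1.5-fold value. Of 124 gene and class values past 1.5-fold, 116 kept their direction in every alternative run. Of the rest, Iigp1 and Ube2c in dendritic cells reversed, and Cd74, H2-Aa and Mmp12 in fibroblasts and Lhfp, Timp3 and Phgdh in dendritic cells had a log2 ratio of 0 once free RNA was subtracted. Reversed means a changed direction in gene values past 1.5-fold, list medians outside the random range or share ratios whose interval excludes 1. Smaller values are not counted. Over all alternatives, 2129 gene values stayed within counting error (241 and 211 with that pseudocount and scaling), 624 moved and 2 reversed. Of the list medians, 625 kept their side of the random range (53 with each) and 8 moved outside it, 2 with a changed sign. A further 27 moved inside with sign kept, and the 3 reversed also lay inside. In tumour cells the medians of MHC class II (0.78 to 1.55), hypoxia (0.45 to 0.65), interferon gamma (0.40 to 0.75) and glycolysis (0.31 to 0.40) kept direction throughout. In macrophages and dendritic cells the subtraction was scaled partly to Cd24a, which they express (114 and 125 CPM in vehicle). It removes too much there, so its values decide nothing. MHC class II in fibroblasts after the subtraction, and type I interferon genes in tumour cells with members of at least 20 CPM, had fewer than 4 members and have no value. Where no cause is named below, the cause was not tested.

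Share ratios over immune cells were 0.903 for macrophages and monocytes, 1.31 for T cells, 1.26 for NK cells, 0.360 for neutrophils and, reversed, 1.08 for dendritic cells. Over cells with a class they were 0.742 for macrophages and monocytes, 1.08 for T cells and 1.15 for tumour cells. The tumour ratio was 1.27 with clusters 13 and 20 and 1.04 without cluster 0. With each library clustered on its own, ratios were 0.830 for T cells, 0.60 for dendritic cells, 1.36 for fibroblasts and 0.367 for neutrophils. At least 1000 UMIs gave 0.431 for neutrophils, whose median depth is low.

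In macrophages, NF-kB targets moved inside the random range at resolution 2.0 (-0.0926), at 1000 UMIs (-0.081), clustered separately (-0.11) and with free RNA subtracted (-0.11). Alternative genes did so at resolution 2.0 (-0.091) and 1000 UMIs (-0.076), histone and DNA modifiers at equal cluster shares (0.045) and with members of at least 20 CPM (0.0554), and type I interferon genes with free RNA subtracted (0.11).

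In tumour cells, proliferation moved inside with clusters 13 and 20 (-0.092), at equal cluster shares (-0.059) and with cells weighted alike (-0.027). Nucleotide synthesis did so at equal shares (-0.054) and with cells weighted alike (-0.081), immediate early genes at equal shares (-0.11) and matrix genes with members of at least 20 CPM (-0.12). Tumour chemokines moved outside with clusters 13 and 20 (0.13).

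In T cells, separate clustering changed the sign of exhaustion genes (0.19, -0.14 otherwise) and proliferation (-0.23, 0.08 otherwise). That setting also brought regulatory (-0.0318), glycolysis (0.090), hypoxia (0.087) and heat shock genes (-0.0072, counted as reversed) inside. Equal shares reversed the regulatory list (0.12), to a value inside the random range. Exhaustion genes moved outside with cells weighted alike (-0.21) and at 10% mitochondrial share (-0.16). Proliferation did so at 1000 UMIs (0.12), at 10% mitochondrial share (0.10) and with doublets kept (0.11).

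In dendritic cells, MHC class II moved inside with free RNA subtracted (-0.089), with cells weighted alike (-0.15) and without sub-clusters 4 and 7 (-0.036). Interferon gamma genes did so clustered separately (0.18), weighted alike (0.048), at 10% mitochondrial share (0.11) and without those sub-clusters (0.0875). Proliferation moved inside weighted alike (0.17). Without those sub-clusters it was -0.057, a reversal to inside the random range, and Iigp1 (-0.49) and Ube2c (-0.080) also reversed.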

Other observations

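No test of a hypothesis is reported in this part, and its genes and clusters were chosen only after the result was seen.

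Cluster 11, led by Ctsk, Acp5 and Atp6v0d2, genes of bone-resorbing osteoclasts, held 175 vehicle cells (1.28%) and 19 WQ-2101 cells (0.111%). It has no class because Mmp9, which osteoclasts share with neutrophils, leads it as well. Tumour clusters also differed between the libraries. Cluster 5, led by Tnnt2, Tubb3 and Krt14, was 3.18% of vehicle and 9.75% of WQ-2101 cells, and cluster 10 was 4.02% and 9.96%. Cluster 5 cells had a median of 13304.5 UMIs in vehicle and 6194 in WQ-2101. Their Ptprc was 6.27 and 13.1 CPM, Lyz2 92.8 and 118, and Rpgrip1, which leads cluster 13 over all other cells, 30.2 and 132. Mixed RNA like that of cluster 13 is therefore not separated from the share of cluster 5. Cluster 2 was 8.67% and 3.39%, and cluster 7 was 8.71% and 4.31%. Cluster 12, led by the interferon gamma genes Iigp1 and Gbp2, was 1.66% and 3.03%.

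Genes of p53 and apoptosis had a median log2 ratio of 0.19 in macrophages and 0.21 in T cells, above the range of random lists, with none of 13 members past 1.5-fold in either. Unfolded protein genes had a median of -0.13 in macrophages, with none of 16 members past 1.5-fold. Genes of the methionine cycle, which supplies methyl groups, lay inside the range of random lists in tumour cells (-0.08), macrophages (-0.07) and T cells (-0.08). The alternatives were not run for these 6 medians.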
